A study of Mus musculus with 4 samples.

How the data were processed

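The 4 libraries were IP and input RNA from WT and from KO macrophages. Groups were taken from the sample titles. The submitters' processing notes name fastp, HISAT2, HOMER, ChIPseeker, StringTie and edgeR and the build mm10, without saying which step each served. The program that called the peaks is not given in the sources used here.

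The authors deposited a list of called peaks for each genotype, IP against input of that genotype, with an annotation of each peak. Each peak has a fold enrichment, a ratio of IP over input, and a p-value, per the file headers, and these are the authors' own values, used only to describe, rank or filter peaks within a list. Both lists hold peaks with a p of at most 0.05. A further deposited table gives, per the file headers, the log2 ratio of KO over WT enrichment at each peak, with a p-value and a false discovery rate, and holds only peaks with a p under 0.05, so peaks tested and not listed are unknown. The gene's input level in FPKM, a level scaled to transcript length and library size, is also deposited there, with the authors' p-value and adjusted p for the input difference, for genes with a listed peak. Of the 6050 peaks, 370 have no level listed. The authors' peaks were called on 1 library pair per genotype and nothing was pooled. No column of values went unused for lack of a sample.

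Peak positions are given as in the lists. The authors assigned each peak to the nearest transcription start, and the assigned gene was compared with RefSeq gene extents of the same build (GRCm38): of peaks whose gene name was found there, 84.9% in WT, 82.7% in KO and 83.6% in the differential table overlapped that gene. Where a named peak did not, the text says so. Of differential peaks annotated to an exon, 19.0% were annotated to an exon of a gene other than the assigned one. Mitochondrial genes carry other symbols in RefSeq and were left out of these shares. Overlap of peaks was computed on exonic blocks with bedtools 2.31.1, with a minimum of 1 base. The lists give the strand of the assigned gene and not of the peak, so overlap ignored strand, although overlap on the same strand had been planned. Shares have exact (Clopper-Pearson) binomial intervals at 95%, and medians have 95% intervals from order statistics.

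Input differences were computed as log2(FPKM + 1) in KO minus WT, a scale that understates the differences of low genes, for genes with a mean of at least 1 FPKM. With 1 library per group no test across genes was run. Each gene list was described by the percentile of its median among 10000 random lists of the same size, matched on mean FPKM in 10 classes, as a description of these libraries. The share of a list's genes whose median peak ratio was below 0 was treated alike. Lists with fewer than 3 listed genes were not placed. The procedure was tested on simulated data over 3679 genes with 100 lists per setting: of lists of 5 genes, 7 with no shift and 93 with a log2 shift of 0.5 fell outside the central 95%, and of lists of 15 genes, 5 and 100 did. Simulated genes varied independently, so this does not show how often lists of genes that vary together fall outside. Of the real lists, only the interferon-stimulated genes had a median as large as the simulated shift. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

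The comparisons, the gene lists and the rule for named genes were set before the data were examined. The lists covered the m6A writer complex, m6A erasers and readers, macrophage identity, Toll-like receptor signalling, negative regulators of inflammatory signalling, pro-inflammatory cytokines and chemokines, interferon-stimulated genes, alternative activation, phagocytosis and lysosome, antigen presentation by MHC class II, cholesterol and lipid handling, proliferation, immediate early genes, p53 targets, and mTOR and stress signalling, and markers of neutrophils, dendritic cells, osteoclasts, B cells, T and NK cells, erythroid cells, mast cells and basophils, stromal cells and blood progenitors. Cd14, Dusp1, Atf3, Mertk, Cxcl10 and Sesn2 each stand in more than 1 list. The rule named all writers, erasers and readers. From the differential table it took the 10 lowest and 10 highest log2 ratios, 1 per gene, in genes with at least 1 FPKM in both inputs and no predicted name. For input levels it took the 10 largest increases and decreases among genes with a mean of at least 5 FPKM that are neither predicted genes nor pseudogenes. For each list it took the 3 members with the largest input difference and up to 3 with the largest peak ratio, and the text names only some of these. Results for a few list members are not reported here. Examples from the lists beyond those 3, and genes named elsewhere, were chosen after their values were seen.

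Alternatives were a stricter peak fold (4), a stricter peak p (1e-10), reciprocal overlap of 50%, a stricter log2 ratio (2 in absolute value), a stricter p of the difference (0.001), expressed genes only, centring on the median, a pseudocount of 0.1, no filter on low values and a minimum mean of 5 FPKM. Others, chosen after seeing the data, were peaks within the RefSeq extent of the named gene, a false discovery rate under 0.05, the peak ratio plus the gene's input log2 ratio, list shifts with only genes whose peak lies in the gene, and random lists matched on peak p. A search of peaks for the m6A sequence motif was planned and not run, since no genome sequence was used here.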

Results

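N6-methyladenosine (m6A), a common internal mark of messenger RNA, was profiled by m6A-seq in mouse macrophages grown from bone marrow for 7 days with macrophage colony-stimulating factor. In m6A-seq, fragmented poly(A) RNA is precipitated with an antibody against m6A (the IP library) and sequenced beside the unprecipitated RNA (the input library). The WT cells carried floxed Mettl3 alleles, and the KO cells also carried a Cre recombinase driven by the gene for lysozyme 2, which acts in myeloid cells. Each genotype had 1 IP and 1 input library, 4 libraries in all, so no difference has a replicate check. The binomial intervals cover counting error only and take peaks as independent. The order-statistic intervals cover only the spread among genes or peaks. The depth of the libraries is unknown here, since the files used hold no read totals.

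The first comparison concerned the deleted gene and the proteins that write, erase and read m6A. Mettl3, the catalytic subunit of the writer complex, had no peak in the WT list and 1 peak in the KO list, in its 3′ UTR on chromosome 14 from 52296089 to 52296658 (build mm10), with the authors' enrichment of 1.35-fold over input. The false discovery rate of that peak was above 0.05. The input level of Mettl3 was not analysed here, so the genotypes could not be checked on the target transcript. Which exons are floxed is not given in the sources used here. All 8 differential peaks of the writer complex, in 6 genes, were lower in KO in the authors' deposited table, and 4 of 8 lay below that table's median. That share of lower genes was at the 89.4th percentile of random lists matched on mean expression and at the 74.97th of lists matched on peak p, inside the central 95% both ways. The log2 ratios of KO over WT in the authors' deposited table were -0.66 for Wtap, -0.60 for Cbll1, -0.58, -0.46 and -0.32 for 3 peaks of Zc3h13, -0.33 for Virma, -0.32 for Rbm15b and -0.18 for Rbm15, all of them partners of the METTL3 enzyme. The Zc3h13 peaks at -0.46 and -0.32 lay within 1 peak of the WT list, so the peak count splits that WT peak. Among erasers and readers, 7 peaks were lower and 2 higher in the authors' deposited table, with 3 below its median. The nuclear reader Ythdc1 had the largest differences there, at -1.18 and -0.97 in the authors' deposited table. The cytoplasmic readers Ythdf2 and Ythdf3 stood at -0.40 and -0.37 and the demethylase Fto at -0.39 in the authors' deposited table. The Ythdc1 peak at -0.97 and the peaks of Fto and Rbm15 had a false discovery rate above 0.05 there. Hnrnpa2b1 and Prrc2a each had 1 lower peak (-0.12 and -0.44) and 1 higher peak (0.37 and 0.20) in the authors' deposited table. Mettl14, Ythdc2 and Igf2bp2 had peaks in the KO list only and Mettl5 in the WT list only. Mettl16, Pcif1, Alkbh5, Fmr1 and Ythdf1 had peaks in both lists and no differential peak. The WT and KO peaks of Mettl16, Alkbh5 and Fmr1 lay at different positions, so these are not shared sites. The peaks of Alkbh5 and Fmr1 and the KO peaks of Mettl16 and Igf2bp2 had a false discovery rate above 0.05. No peak was listed for Igf2bp1, Igf2bp3 or Hnrnpc.

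Input levels of these genes were slightly higher in KO. All 12 with a listed level were above 0, or 11 of 12 once the median difference of all listed genes was subtracted, where Prrc2a turned negative. Ythdf2 stood at 9.70 FPKM in WT and 12.6 in KO, Cbll1 at 4.22 and 5.40, Wtap at 10.1 and 12.4, and Ythdc1 at 3.59 and 4.48. The median log2 difference over the 12 genes was 0.20 (95% order-statistic interval 0.14 to 0.28), at the 99.6th percentile of 10000 random lists matched on mean expression. Those lists were not matched on peak direction. All 6 listed writer genes and 4 of 6 listed erasers and readers had lower peaks only, and all listed genes of that kind had a median of 0.10. The same input libraries enter the peak ratio, so part of this position may follow from how these genes came to be listed.

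The second comparison asked how many m6A peaks each genotype showed and where on transcripts they lay. The WT list held 16709 peaks assigned to 9875 genes and the KO list 21031 peaks assigned to 11675 genes. Peaks were named in both lists for 8515 genes, in WT alone for 1360 and in KO alone for 3160. Most peaks lay in 3′ UTRs, 59.6% (58.9 to 60.4, exact binomial interval) in WT and 64.1% (63.4 to 64.7) in KO, while 5′ UTRs held 13.0% (12.5 to 13.5) in WT and 10.3% (9.86 to 10.7) in KO, and other exons held 27.4% and 25.6%. The extra peaks of the KO list lay mostly among the weak ones. KO peaks were also shorter (median exonic length 330 bases, against 391 in WT) and less enriched (median 3.15-fold, against 3.74). With at least 4-fold enrichment the lists held 8027 and 8516 peaks, and at a peak p of 1e-10 or lower they held 5140 and 5143. The summed exonic length of all peaks was 11937 kb in WT and 12357 kb in KO. At the stricter settings it was smaller in KO: 8904 kb in WT and 8102 kb in KO at 4-fold, and 6407 kb and 5325 kb at that p. Peak number also depends on read depth, which differs between libraries to an unknown extent.

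Peaks of WT cells lay mostly where KO cells had a peak too. Of the WT peaks, 12258 (73.4%, 72.7 to 74.0) shared at least 1 exonic base with a KO peak, and 12947 of the KO peaks (61.6%, 60.9 to 62.2) shared one with a WT peak. Sharing followed peak strength within each list: it reached 95.4% in the strongest of 10 equal classes of WT peaks by enrichment and 64.8% in the weakest, against 88.6% and 45.2% in the KO list. When overlap had to cover 50% of both peaks, 46.4% of WT and 35.7% of KO peaks were shared.

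The third comparison concerned differences of enrichment between genotypes at single peaks. Lower m6A enrichment in KO was the more common direction, and most differences were modest. The authors' deposited table listed 6050 peaks, of which 4212 (69.6%, 68.4 to 70.8) were lower in KO and 1838 were higher. The median log2 ratio of the lower peaks was -0.55 in the authors' deposited table, which is 0.683 of the WT enrichment, and that of the higher peaks was 0.62. Lower peaks alone were found in 3034 genes, higher peaks alone in 1369 and both in 328. Of the lower peaks, 92.7% still overlapped a peak of the KO list, and of the higher peaks 64.7% overlapped a peak of the WT list. The p-values in this table compare the reads of these libraries, not the genotypes, and every listed peak has a p below 0.05. At a false discovery rate under 0.05, 4815 of the 6050 peaks remained. Named peaks left out at that rate include those of Smchd1, Banp, Mllt11, Nfatc1, Cd79b, Tfeb, Klf2 (-0.67), Ciita (-0.89) and Mki67 (0.87) in the authors' deposited table. Set against the table's own median of -0.40, 3023 peaks were lower and 3014 higher (50.1% lower), a split that follows from the centring itself. The ratio carries no outside standard for total m6A.

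Direction depended on the part of the transcript and on transcript level. In the authors' deposited table, 88.7% of differential peaks in 5′ UTRs (85.9 to 91.1) and 85.2% of those in other exons (82.9 to 87.3) were lower in KO, against 63.2% (61.8 to 64.6) in 3′ UTRs. Among peaks in the most abundant of 5 equal classes of transcripts, with a mean input of at least 21.5 FPKM, only 44.3% (41.4 to 47.2) were lower, and in 3′ UTRs of these transcripts 36.5% (33.3 to 39.7), while 75.7% of their 5′ UTR peaks and 71.5% of their other exon peaks were lower. Within this most abundant class direction turned with peak strength. Lower peaks made up 90.8% (86.7 to 94.0) of the strongest p class, 55.9% (48.4 to 63.1) of the second and 20.9% (15.5 to 27.2) of the weakest. Over all classes, genes of ribosomal proteins had 10 lower and 44 higher peaks in the authors' deposited table. Peaks with the strongest own p were almost all lower (96.4% of the strongest of 5 classes), and 41.6% of those in the weakest class were lower.

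**Figure D1:**
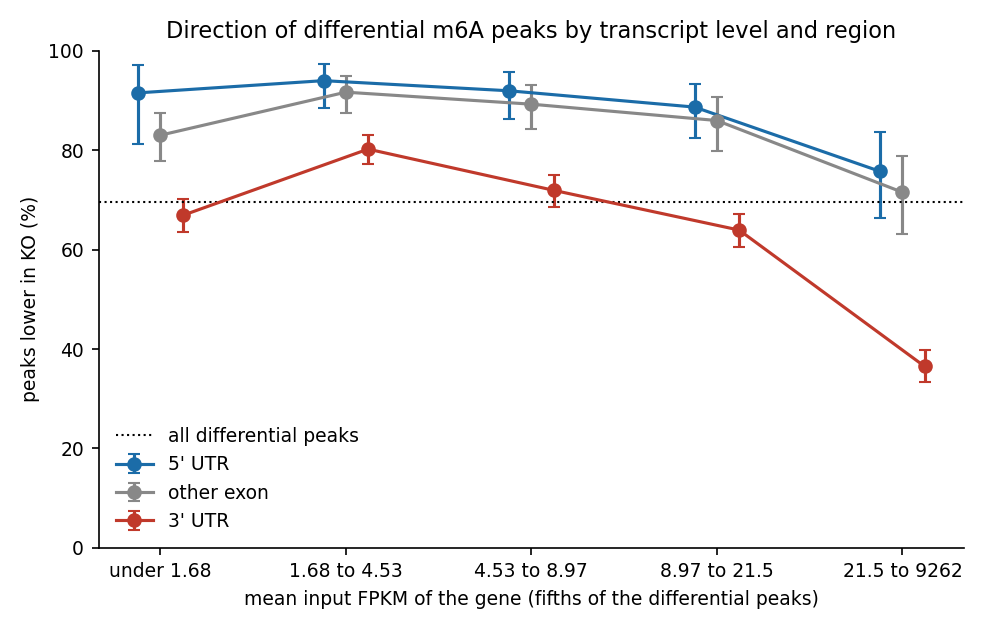
Share of differential m6A peaks lower in KO (%) against the mean input FPKM of the gene, in 5 equal classes of the differential peaks, for 5′ UTR, other exon and 3′ UTR peaks, with exact binomial 95% intervals and a dotted line at 69.6%, the share among all differential peaks. In the most abundant class 36.5% of 3′ UTR peaks were lower, against 75.7% of 5′ UTR peaks.

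In the fixed list of Toll-like receptor signalling, a pathway that senses microbial products, differential peaks were lower in KO. Of 25 members 20 had a WT peak and 14 a differential one, and all 22 differential peaks were lower in KO in the authors' deposited table, whereas 9 of 22 lay below the table's median. The receptors Tlr4, for lipopolysaccharide, and Tlr3, for double-stranded RNA, had peaks at -0.64 and -0.58 in the authors' deposited table, and the adaptor Ticam1 reached -0.83 and the kinase Irak2 -0.75. The share of genes with lower peaks, 100%, was at the 100th percentile of random lists matched on mean expression, whose median was 57.1%, and at the 97.8th percentile of lists matched on peak p, whose median was 85.7%, a matching chosen after seeing the data. The size of the ratio did not stand apart: the list's median over genes, -0.31, was at the 35.4th percentile.

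Immediate early genes, transcribed within minutes of a stimulus, showed the same direction, with 13 lower peaks and 1 higher in the authors' deposited table and 6 of 14 below the table's median. The transcription factors Fos and Klf2 had peaks at -0.86 and -0.67 and Myc at -0.54 in the authors' deposited table. The list's share of genes with lower peaks was at the 99.98th percentile matched on mean expression and at the 94.5th matched on peak p. All 4 peaks of p53 targets were lower, among them those of Aen (-0.54) and Mdm2 (-0.48), the ubiquitin ligase that restrains p53, in the authors' deposited table, and 2 of 4 lay below its median. The peak assigned to Phlda3 lay in Csrp1, and the share of lower genes was inside the central range (82.4th percentile, and 62.9th matched on peak p).

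Other lists went both ways. Negative regulators of inflammatory signalling had 11 lower and 5 higher peaks in the authors' deposited table, or 5 below its median. Irak3, an inhibitor of Toll-like receptor signalling, had 2 lower peaks in its 3′ UTR, at -1.13 (chromosome 10, 120142872 to 120143022) and -0.68, and the phosphatase Inpp5d had 1 at -0.57, while Nfkbia, the inhibitor of NF-κB, had a higher peak at 0.80 in the authors' deposited table. The 2 Irak3 peaks lay within 1 peak of the WT list. Of 3 higher peaks that the authors' deposited table assigned to the phosphatase Ptpn6, that at 0.46 lay in the gene and those at 1.04 and 0.99 lay in Grcc10, and the higher peak assigned to Tnip1, at 0.41, lay in Anxa6. Macrophage identity genes had 11 lower and 7 higher peaks in the authors' deposited table, with 2 below its median: Fcgr1, a receptor for immunoglobulin G, stood at -0.70, the lineage transcription factor Spi1 at -0.68, and the surface marker Adgre1 at 0.54. The median ratio over the genes of this list, -0.10, was at the 2.495th percentile of lists matched on mean expression, whose median was 0.37, a position lost without the filter on low values. The position of this list for the share of lower genes turned with the matching, at the 98.0th percentile matched on mean expression and at the 0.525th matched on peak p. Interferon-stimulated genes had 4 lower and 2 higher peaks in the authors' deposited table, 1 of them below its median, with the ubiquitin-like Isg15 at -0.65 and the antiviral membrane proteins Bst2 and Ifitm3 at 0.49 and 0.32. Alternative activation genes had 5 lower and 2 higher peaks there, 3 of them below the median, with a receptor subunit for interleukin 4, Il4ra, at -0.49 and Stat6, which acts downstream of it, at -0.42 and 0.54 in the authors' deposited table. The Stat6 peak at 0.54 also lay in the extent of Nab2, so it may belong to either gene.

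Cytokine and lipid handling transcripts had more higher than lower peaks. All 3 peaks of pro-inflammatory cytokines and chemokines were higher in KO in the authors' deposited table, at 1.08 for Tnf, 0.51 for Ccl9 and 0.36 for Ccl6, and none of them lay below its median. Cholesterol and lipid handling genes had 4 lower and 7 higher peaks in the authors' deposited table, with 3 below its median: the fatty acid binding protein gene Fabp5 had peaks at 0.90 and 0.44 and the lipid droplet coat gene Plin2 had one at 0.72. Phagocytosis and lysosome genes divided evenly, 6 lower and 6 higher (2 below the median), with the lysosomal transcription factor Tfeb at -1.03 in the authors' deposited table. Antigen presentation genes also divided evenly, 3 and 3 (2 below the median), with the co-stimulatory Cd80 at 1.55 and the class II transactivator Ciita at -0.89 and -0.56 in the authors' deposited table. The proliferation list had 3 lower and 3 higher peaks in the authors' deposited table (3 below its median), 4 of them in Mki67, a marker of cycling cells, from -1.40 to 0.87. The shares of lower genes for cytokines and for lipid handling were inside the central 95% matched on mean expression (6.35th and 14.6th percentile) and below it matched on peak p (1.23th and 0.435th). Atf4 (0.90) and Tsc2 (0.86), from the mTOR and stress list, were higher in the authors' deposited table. The Tsc2 peak also lay in the extent of Pkd1, so it may belong to either gene.

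**Figure D2:**
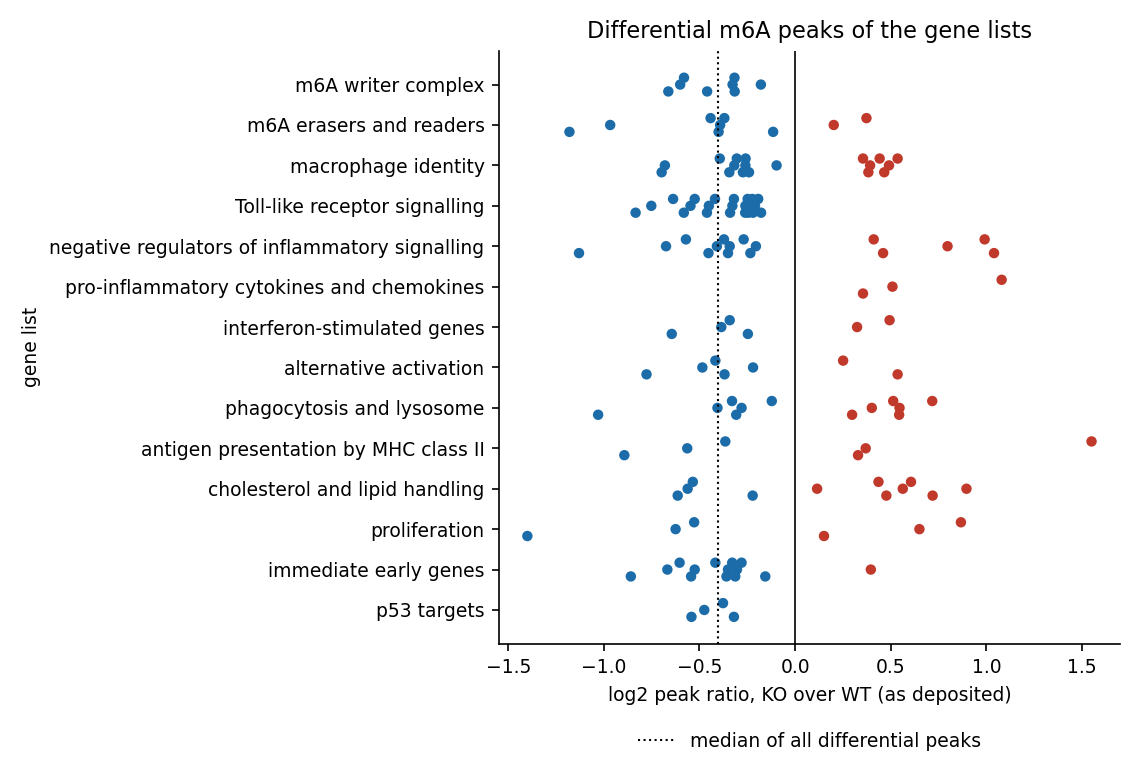
Log2 peak ratios of KO over WT (horizontal axis, as deposited) of the differential peaks of each gene list with at least 3 such peaks, 1 point per peak, blue below 0 and red above, with a dotted line at the table's median of -0.40. All 22 peaks of the Toll-like receptor list lie below 0 and 9 of them below the dotted line, and the 3 of the cytokine list lie above both.

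Among named genes with at least 1 FPKM in both inputs, the largest single ratios belonged to a mixed set of transcripts, while the whole of the authors' deposited table ran from -9.36 to 10.2. Among lower peaks, the authors' deposited table gave -4.94 for the histone gene H3c14 (chromosome 3, 96246684 to 96247102, 5′ UTR), -4.46 for the phosphatase subunit gene Ppp2r3c (chromosome 12, 55281472 to 55281713, 3′ UTR), -3.07 for a peak within Smchd1 that is annotated to an exon of another gene, and -2.82 for Ndufs4, a subunit of respiratory complex I. The mitochondrially encoded mt-Atp8 and mt-Nd4 stood at -4.70 and -4.69 in the authors' deposited table. A peak at -5.63 assigned to mt-Co3 (7956 to 8607) was annotated to an exon of mt-Atp8, but it overlapped ATP6, ATP8 and COX3 in RefSeq. The peak of mt-Atp8 ended at 7969, so most of the -5.63 peak lay beyond it. Listed WT input levels were low, at 8.49 FPKM for mt-Atp8, 3.35 for mt-Nd4 and 5.45 for mt-Co3. Among higher peaks, the authors' deposited table gave 5.59 for Sumo2, a protein modifier (chromosome 11, 115523699 to 115530029, 3′ UTR), 4.63 for Cflar, an inhibitor of caspase-8 (chromosome 1, 58722856 to 58723006, exon), 3.59 for Tulp4, 3.08 for Banp, 3.07 for the cold-induced RNA-binding protein Rbm3, 3.01 for the initiation factor subunit Eif3j1 and 2.69 for the splicing-associated Thrap3. Reads shared with near-identical copies leave uncertain the ribosomal protein values of the authors' deposited table, at 5.70 for Rpl7a, -6.25 for Rpl35a-ps6, -5.47 for Rpl17-ps5, -3.00 for Rps13-ps1 and 2.44 for Rpl35a-ps2. The peak at 2.81 that the authors' deposited table assigned to Mllt11 lay in Cdc42se1. Cflar also had a lower peak in its 3′ UTR, at -0.68 in the authors' deposited table.

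The fourth comparison concerned transcript levels in the input libraries. Levels were listed for 4403 genes, all of them genes with a differential peak, and 3679 had a mean of at least 1 FPKM. Among the better expressed genes, with a mean of at least 5 FPKM and leaving out predicted genes and pseudogenes, the largest decreases on log2(FPKM + 1) were those of the monoacylglycerol lipase gene Mgll (105 FPKM in WT, 47.5 in KO), Rn7sk (a log2 difference of -1.01), the cysteine dioxygenase gene Cdo1 (8.69 and 4.24), Bex1 (68.9 and 36.8), Ppia (175 and 100.2) and the cell cycle inhibitor gene Cdkn1c (113 and 66.8). The complement gene C1qb stood at 545 FPKM in WT and 326 in KO, Gpnmb at 1839 and 1145, and the calprotectin genes S100a9 and S100a8 at 155 and 90.2 and at 77.7 and 46.4. The largest increases were those of Rpl21 (3.35 FPKM in WT, 21.9 in KO), Evi2b (9.76 and 29.5), the interferon-inducible genes Ly6e (14.0 and 31.7) and Rtp4 (8.14 and 18.1), Tomm6, a part of the mitochondrial import pore (18.3 and 37.9), the aspartic protease gene Ctse (8.57 and 17.3), the endocytic adaptor gene Dab2 (23.9 and 46.3), Sfi1 (a log2 difference of 0.92), the matrix protein gene Thbs1 (7.95 and 15.5) and Tgfbi (13.4 and 24.8). Rpl21 and Ppia have many near-identical copies in the genome and Rn7sk is a small RNA without a poly(A) tail, which leaves their values uncertain.

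Large differences were few. At 2-fold or more, 11 genes were higher and 9 lower in KO, or 6 and 3 without predicted genes and pseudogenes. These were Rpl21, Evi2b, Ly6e, Rtp4, Tomm6 and Grem1 on the higher side and Mgll, Rn7sk and Ighg2b on the lower side, of which Grem1 and Ighg2b were singled out after their values were seen. With a pseudocount of 0.1 in place of 1, 20 genes were higher. The median log2 difference over all 3679 genes was 0.07. The authors' deposited table marked 19 genes as different in input, and the smallest adjusted p it gave was 0.562.

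Of 25 interferon-stimulated genes, 5 had a listed level, and all 5 were higher in KO input, with Isg15 at 8.83 FPKM in WT and 14.8 in KO, Ifit3 at 7.35 and 12.4, Ifitm3 at 144 and 217, and Bst2 at 83.5 and 90.7. Their median log2 difference, 0.59, exceeded those of all 10000 matched random lists. Of 11 antigen presentation genes, 5 had a listed level, with a median of 0.28 (99.5th percentile) and 4 of 5 above 0. The class II chains H2-Aa and H2-Eb1 stood at 77.2 and 99.1 FPKM and at 87.4 and 114. Negative regulators of inflammatory signalling had a median of 0.17 (97.6th percentile) and 9 of 11 members above 0, with Dusp1 at 5.98 and 7.56 FPKM, Cyld at 3.82 and 4.66 and the mRNA decay factor Zfp36 at 18.1 and 21.4. Erasers and readers, at 0.20, were at the 97.9th percentile.

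Cholesterol and lipid handling genes lay on the other side. Their median was -0.14, at the 0.31th percentile, with Fabp4 at 58.7 FPKM in WT and 39.5 in KO, Fabp5 at 478 and 364 and the lipoprotein lipase gene Lpl at 377 and 341, although the cholesterol exporter genes Abca1 (28.6 and 33.5) and Abcg1 (a log2 difference of 0.20) were higher. These 5 lists, of 14 with at least 3 listed genes, were outside the central 95% of random lists, which were not matched on peak direction. With only genes whose peak lies in the gene, negative regulators moved inside that range and the writer complex moved outside it.

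The other lists stayed inside that range. The writer complex (median 0.21, 97.3th percentile) and cytokines (0.25, 97.1th percentile), with Ccl9 at 71.0 and 99.4 FPKM, were near its edge. Immediate early genes had a median of 0.15 (95.9th percentile), with Fos at 9.10 FPKM in WT and 16.9 in KO and Egr2 at 16.5 and 13.3. Toll-like receptor genes had a median of 0.10 (79.5th percentile), with Tlr2 at 21.9 and 34.2 FPKM, Tlr4 at 17.1 and 22.9 and Cd14, a co-receptor for lipopolysaccharide, at 153 and 198. Medians were 0.13 for proliferation (77.8th percentile), 0.08 for alternative activation (67.9th), 0.06 for p53 targets (36.3th) and 0.02 for phagocytosis and lysosome (45.4th). Macrophage identity genes had a median of -0.02 (22.7th percentile), with the lysozyme gene Lyz2 at 10533 FPKM in WT and 6615 in KO, Fcgr1 at 40.6 and 58.4, Apoe at 8313 and 8180 and Adgre1 at 247 and 269.

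Markers of other cells that bone marrow cultures can hold were seldom listed. The neutrophil genes S100a8 and S100a9 were both lower in KO, at 0.597 and 0.581 of the WT level. The dendritic cell list had Itgax at 71.9 FPKM in WT and 46.7 in KO and Irf8 at 27.6 and 27.4, and the osteoclast list had Atp6v0d2 at 274 and 201 and Nfatc1 at 7.00 and 8.34. Each of these 3 lists had 2 differential peaks in the authors' deposited table, with Itgax at 0.25 and Irf8 at -0.43, S100a8 at 0.64 and S100a9 at 0.55, and Nfatc1 at 0.75 and Atp6v0d2 at 0.40. The B cell list had 1, at 1.45 in Cd79b. The lists for T and NK cells, erythroid cells, mast cells and basophils, stromal cells and blood progenitors had 0 differential peaks, so their input levels were not analysed here. Of genes outside these lists that stromal cells are known to express, 5 chosen after their values were seen had low levels, Grem1 at 0.883 FPKM in WT and 3.04 in KO, Aebp1 at 0.962 and 2.86, Cald1 at 0.347 and 0.967, Cdh11 at 0.156 and 0.491 and Prrx1 at 0.0927 and 0.268.

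**Figure D3:**
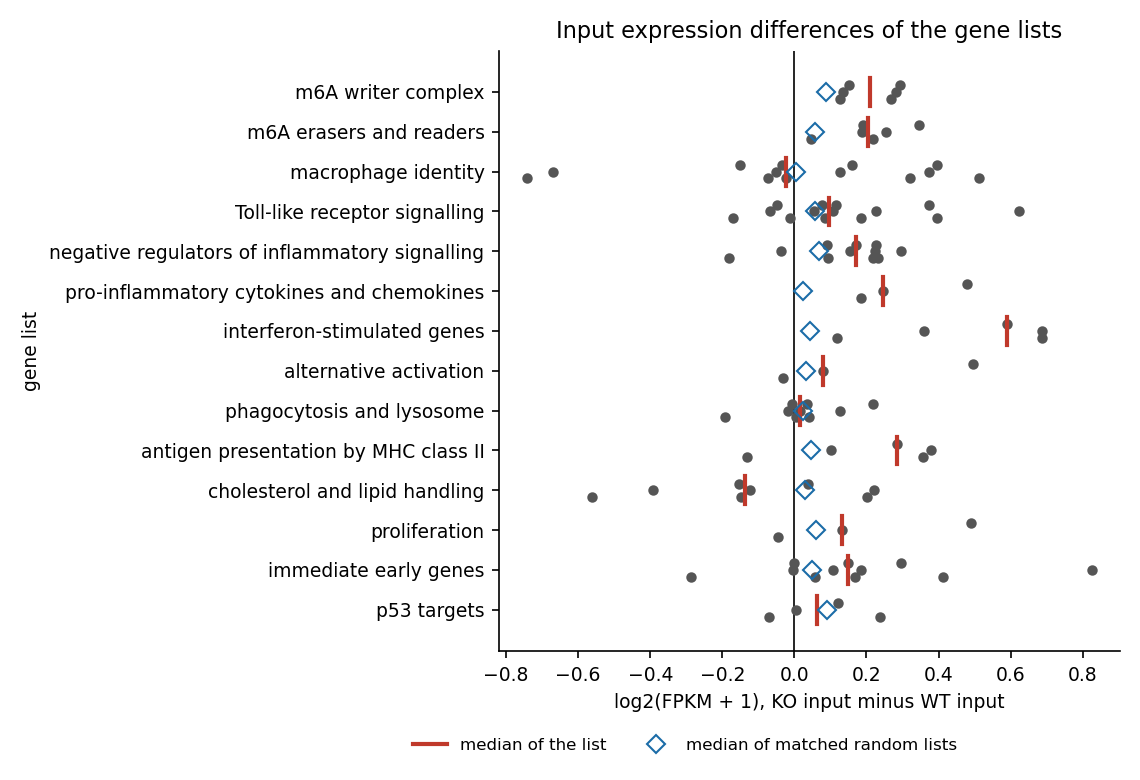
Differences of log2(FPKM + 1), KO input minus WT input (horizontal axis), for the listed members of each gene list with at least 3 of them, 1 grey point per gene, with the median of the list (red bar) and the median of 10000 random lists matched on mean expression (blue diamond). The interferon-stimulated genes have the highest median, at 0.59, and the cholesterol and lipid handling genes the lowest, at -0.14.

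The last comparison set m6A change against transcript level. The 2349 genes with lower peaks only had a median input difference of 0.10 (95% order-statistic interval 0.098 to 0.110), and 77.4% of them were above 0. The 1046 genes with higher peaks only had a median of 0.00 (-0.01 to 0.01), with 50.3% above 0, and the 284 genes with both kinds had 0.07. Fos, with a lower peak, and Fabp4, with a higher one, are examples of the lists with opposite signs, whereas Ly6e had a higher peak and a higher level. The first group exceeded all 10000 random lists matched on mean expression, whose median was 0.08, and the second lay below all of them. Across the 3679 genes, which are not independent replicates, Spearman's rho between the gene's median peak ratio and its input difference was -0.29 and Pearson's r was -0.23, and in 10 of 10 classes of mean expression genes with lower peaks had the higher median. The same input libraries enter both quantities, so chance alone pushes this relation below 0, and without read counts the size of that effect could not be simulated.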

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

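Peak counts were lower at stricter thresholds. At 4-fold enrichment the lists held 8027 WT and 8516 KO peaks, and at a peak p of 1e-10 they held 5140 and 5143. At both settings the summed exonic length of KO peaks was below that of WT peaks (8102 against 8904 kb, and 5325 against 6407 kb). Shared peaks were 46.4% of WT and 35.7% of KO peaks with reciprocal overlap of 50%, and 78.7% and 68.4% at 4-fold, where 3′ UTRs held 58.3% and 59.7%. In the authors' deposited table, 98 peaks were lower and 67 higher (59.4% lower) at an absolute log2 ratio of 2, and 2319 and 785 (74.7%) at a p of 0.001. Centring gave 3014 higher peaks and 50.1% lower. Among alternatives chosen after seeing the data, the share lower was 72.1% for peaks within the named gene, 71.6% at a false discovery rate under 0.05 and 68.1% with the gene's input ratio added. In input, 20 genes were higher with a pseudocount of 0.1, and 5 were lower at a mean of 5 FPKM. Genes with lower peaks had a median input difference of 0.12 with that pseudocount and 0.0901 at an absolute log2 ratio of at least 2, where the median of genes with higher peaks turned to -0.0692. With only genes whose peak lies in the gene, 5 lists again lay outside the central range in input, but the writer complex replaced negative regulators. The macrophage identity list turned from the 98.0th to the 0.525th percentile for its share of lower genes when matched on peak p. Counting each main value once per alternative setting, 25 such comparisons moved, 1 reversed and 23 stayed. Other values, mostly of single lists, were counted apart: 10 moved, 1 reversed, 1 was weaker, 2 were stronger and 48 stayed. The motif search was not run. No paired analysis was possible because each genotype had 1 library per fraction.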

Other observations

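Pathways annotated by the authors were examined only after the fixed lists, so these groups were chosen after seeing the data. Of 37 spliceosome genes, 14 had a median peak ratio below 0, and the median over genes was 0.43 in the authors' deposited table (99.98th percentile, random median -0.32), with Srsf9 at 1.30 and Tra2b at 1.23. Oxidative phosphorylation, with 48 genes, had a median of 0.46 (99.97th percentile, random median 0.12). Its largest peak ratios in the authors' deposited table were nevertheless lower in KO. These were of peaks assigned to mt-Co3 (-5.63, overlapping ATP6, ATP8 and COX3 in RefSeq), mt-Atp8 (-4.70) and mt-Nd4 (-4.69). Its median input difference was -0.05 (0.02th percentile), with Uqcrb at 56.3 FPKM in WT and 48.6 in KO and Ndufs5 at 32.8 and 26.8. Proteasome genes had a median peak ratio of 0.42 (97.9th percentile), with Adrm1 at 1.37 in the authors' deposited table. RNA degradation (29.2th percentile), protein processing in the endoplasmic reticulum (49.5th), ubiquitin mediated proteolysis (60.4th), ribosome biogenesis (84.2th) and cell cycle (21.5th) stayed inside the central range for peaks. So did the authors' Toll-like receptor pathway (42.8th), wider than the fixed list, where 27 of 35 genes had a median ratio below 0. These percentiles are of the median ratio, on which the fixed Toll-like receptor list was also inside the range (35.4th). The share of lower genes, on which that list stood apart, was not placed for pathways. Of 208 pathways, 18 lay above the central 95% of matched lists for peaks and 1 below it, where 5.2 would be expected on each side. Pathways share genes and were not tested as independent. The random lists for peaks were matched on mean expression and not on peak p. Direction also turned with peak p, so these positions may reflect peak strength.

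For input levels, 9 of the 208 pathways lay above the central 95% of matched lists and 16 below it. Antigen processing and presentation (21 genes, 96.5th percentile) and cholesterol metabolism (13 genes, 10.4th) stayed inside. The fixed lists for antigen presentation and for cholesterol and lipid handling had been outside. The TNF pathway (30 genes) had a median of 0.17 (99.94th percentile) and the RIG-I-like receptor pathway (19 genes) 0.19 (99.69th), whereas NF-kappa B signalling (59.5th), NOD-like receptor signalling (73.7th), IL-17 signalling (52.2th), chemokine signalling (46.2th) and the Toll-like receptor pathway (89.1th) stayed inside. Ferroptosis genes had a median of -0.07 (0.39th percentile), with the cystine transporter gene Slc7a11 at 3.08 FPKM in WT and 1.25 in KO. Tfrc stood at 46.5 and 37.4, whereas Steap3 was higher in KO, at 23.5 and 31.1. Single genes picked out after their values were seen, which stand for no group, were Ccr2, a chemokine receptor gene, at 3.63 and 6.12 FPKM, Csf1, the gene of macrophage colony-stimulating factor, at 1.94 and 3.14, Trex1 at 11.8 and 20.3, and Irgm1 at 7.75 and 11.8.

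The tests weighed from here were chosen after the results were seen, except those on input level and on shared reads, which were written before their values were computed. In the most abundant transcripts most differential peaks in 3′ UTRs were higher in KO. Those in 5′ UTRs and other exons, and those of the strongest class of peak p, were mostly lower. A fall of the gene's input level was not the source, since 97.0% of the higher peaks stayed above 0 with the input ratio added. Reads shared among ribosomal protein genes, predicted genes and pseudogenes were not the source either, since 55.0% (51.9 to 58.0) were higher without such genes, against 23.3% (22.0 to 24.7) in the other transcripts; reads shared by other genes with copies, such as Ppia, were not tested. Unspecific IP background from abundant transcripts stays open: the higher peaks there had a median KO enrichment of 2.11-fold (2.03 to 2.17), against 3.45-fold (3.14 to 3.93) for the lower ones, but higher peaks were also the weaker ones in all 4 other classes of transcript level, so this value does not single out abundant transcripts.

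Lyz2 was lower in KO input. Fewer macrophages in the KO culture would lower the other identity genes, whose median difference was 0.0515 (-0.07 to 0.37). Fewer neutrophils, which also express Lyz2, stay open: S100a8 and S100a9 were reduced to 0.597 and 0.581 of WT and Lyz2 to 0.628, and their joint loss was 2.46% of the Lyz2 loss in FPKM, which decides nothing without the ratio of these transcripts in neutrophils. The Cre gene placed at the Lyz2 locus stays open: 97.9% of 187 other genes above 100 FPKM were less reduced than Lyz2, but 4 (C1qb, Gpnmb, Ppia and S100a9) were reduced as much or more, and the size of the difference alone does not point to the locus.

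The 5 listed interferon-stimulated genes were higher in KO input. A trend with abundance in the FPKM scale would also shift random lists matched on mean FPKM, whose median was 0.04, against 0.59 for these genes. This repeats the position given above and is not a separate test. More dendritic cells in the KO culture could not be tested, since only 2 dendritic cell markers had a listed level, and neither was higher (Itgax at 71.9 FPKM in WT and 46.7 in KO, Irf8 at 27.6 and 27.4). A difference between cultures or litters may account for it as well, and with 1 library per genotype that cannot be told from an effect of Mettl3.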
